A study of Mus musculus with 6 samples.

How the data were processed

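Gene expression was measured in 4T1 cells, a mouse mammary carcinoma line that lacks oestrogen receptor, progesterone receptor and HER2, after 24 h of culture with mouse bone marrow-derived macrophages. The macrophages had been polarised to a pro-inflammatory (PI) or an anti-inflammatory (AI) state before the co-culture. Per the labels' protocols, macrophages were then labelled with CD11b microbeads and removed on a depletion column, and total RNA of the remaining tumour fraction was turned into biotinylated cDNA and hybridised to Affymetrix arrays. The group and replicate number of each array were taken from its title, which gives 3 PI and 3 AI arrays. Per the series design, replicates used macrophages from individual mice, so the spread between arrays of a group covers different mice, while the tumour cells were the same line throughout.

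The deposited values are log2 expression values per transcript cluster, the array's gene-level probe set. Affymetrix Expression Console and RMA are named, without versions, in the submitters' processing notes. RMA corrects for background, normalises the arrays to a shared distribution of intensities and summarises probes on the log2 scale. The genome build and the array's annotation version are not given in the sources used here, so no coordinates are reported. The 2 deposited tables held the same log2 values for 41345 transcript clusters on 6 arrays, with 0 differing values, from 1.33 to 13.89. The number of unused per-sample columns was 0. Per the file headers, the deposited table also holds the authors' p-value, q-value and fold for each cluster. The authors' fold equalled 2 to the power of the AI mean minus the PI mean for all 41345 clusters within 1e-05, so it is a ratio of AI over PI. Their test is not stated, and the p-value column lay within 1 percent of an unpaired equal-variance test for all 41345 clusters, with q-values equal to the Benjamini-Hochberg adjustment of those p-values to the same tolerance. All fold changes of this re-analysis are given as PI over AI, the opposite direction to the authors' column.

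Of the clusters, 24724 carried 1 gene symbol, 2313 carried several and 14308 carried none in the deposited table. Only clusters with 1 symbol were used for the gene tests. Symbols were updated through the Entrez identifier with a RefSeq gene table of assembly GRCm38.p6, used for names only. It held the identifiers of 23652 of those clusters, and 2473 symbols changed. Each gene was represented by its cluster with the highest mean over the 6 arrays, which left 23385 genes, 1064 of them with more than 1 cluster. Genes present only on clusters shared with other genes were not tested as genes.

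PI was compared with AI by limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values and group as the only term. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 23385 genes, with a threshold of 0.05. No filter on dim genes was applied. Gene groups were 31 lists of pathways and 10 lists of cell type markers. Of 845 members written in these lists, 791 were measured. Lists were tested with limma's camera, which compares a list's members with all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 41 lists. Camera with the correlation estimated for each list, and the rotation test fry, were run beside it. Tables were prepared and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

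The groups, gene lists, tests, thresholds and most alternative settings were chosen before the data were examined. So was the rule for naming genes. It took up to 12 genes per direction with the largest change among those past the threshold whose PI and AI arrays did not overlap, leaving out predicted genes. Where no gene passed in a direction, it took the 8 with the smallest p, as values. For each list described it took up to 4 members past the threshold with the smallest p, or up to 2 members as values where none passed. Itgam, Cd68, Adgre1, Csf1r, Ptprc, Lyz2, Nos2 and Arg1 were always named. A gene that the rule takes is not reported here by name, although it enters all counts. Genes named outside this rule are marked as chosen after their values were seen.

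The number of arrays limits the precision. The median standard error of a log2 fold change was 0.11, and the median 95% interval reached 0.20 to either side among genes of the highest level and 0.28 among those of the lowest, with genes divided into 4 equal groups by level. The fit was tested on simulated data for the PI against AI comparison, with 23385 genes of which 200 were changed. It recovered 23 of 50 genes changed by 0.5 on the log2 scale and 46 of 50 changed by 1. Of genes changed by 1.5 and 2, it recovered 49 of 50 and 50 of 50. It called 7 of 23185 unchanged genes. The simulated noise was normal, independent between genes and set to the moderated variances, so these shares may overstate recovery in the data. Of the 25 measured genes that differed by at least 1 on the log2 scale, 15 passed. Alternatives were the replicate number as a block, further normalisations, a filter on level, averaging of clusters, other variance models and thresholds, a floor at the 20th percentile, and leaving out each array in turn.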

Results

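The study asked how the polarisation of macrophages affects gene expression in tumour cells cultured with them. Expression of 23385 genes was measured in 4T1 mouse mammary carcinoma cells after 24 h of co-culture with PI macrophages (3 arrays) or AI macrophages (3 arrays), with macrophages removed by CD11b depletion before RNA extraction. Values are RMA expression levels on the log2 scale, and differences are PI minus AI. No arrays of 4T1 cells without macrophages were compared. A gene said to rise or fall was therefore higher or lower in PI than in AI. Whether the PI or the AI co-culture changed it cannot be told. Across all transcript clusters the correlation between any pair of arrays lay between 0.987 and 0.990. The first principal component held 26.1% of the variance, with scores of 0.17 to 0.50 for the PI arrays and -0.52 to -0.29 for the AI arrays.

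The tumour fraction of the PI co-culture had higher levels of a set of interferon-inducible genes. Iigp1, an interferon-inducible GTPase of cell-autonomous immunity (transcript cluster 17350925, Entrez 60440), rose the most, from 7.16 ± 0.24 in AI to 9.79 ± 0.17 in PI (SD, n = 3 each), a 6.22-fold difference with a 95% interval of 4.95 to 7.81 (limma adjusted p = 0.00309). Cxcl9, a chemokine that attracts activated T cells (cluster 17449710, Entrez 17329), rose 5.64-fold, from 4.45 ± 0.39 to 6.95 ± 0.40 (SD, n = 3 each; limma adjusted p = 0.0208). Nos2, the inducible nitric oxide synthase, rose 1.93-fold, from 6.49 ± 0.04 to 7.44 ± 0.18 (SD, n = 3 each; limma adjusted p = 0.0319).

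In all, 17 of 23385 genes passed an adjusted p of 0.05 in limma, and all 17 were higher in PI, by 1.79-fold to 6.22-fold. For each of the 17, the 3 PI arrays lay above the 3 AI arrays. Besides genes of the lists below, they held Gbp2b, a guanylate-binding protein (listed as Gbp1 in the deposited table), with a log2 fold change of 1.66, and Uba7, the activating enzyme for the ubiquitin-like protein ISG15, at 1.13. The remaining genes outside the lists were the predicted gene Gm4841 at 2.19 and AW112010 at 0.84. Uba7, Gm4841 and AW112010 lie outside the naming rule and were chosen after their values were seen. Of the 17, 15 differed by at least 1 on the log2 scale.

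**Figure D1:**
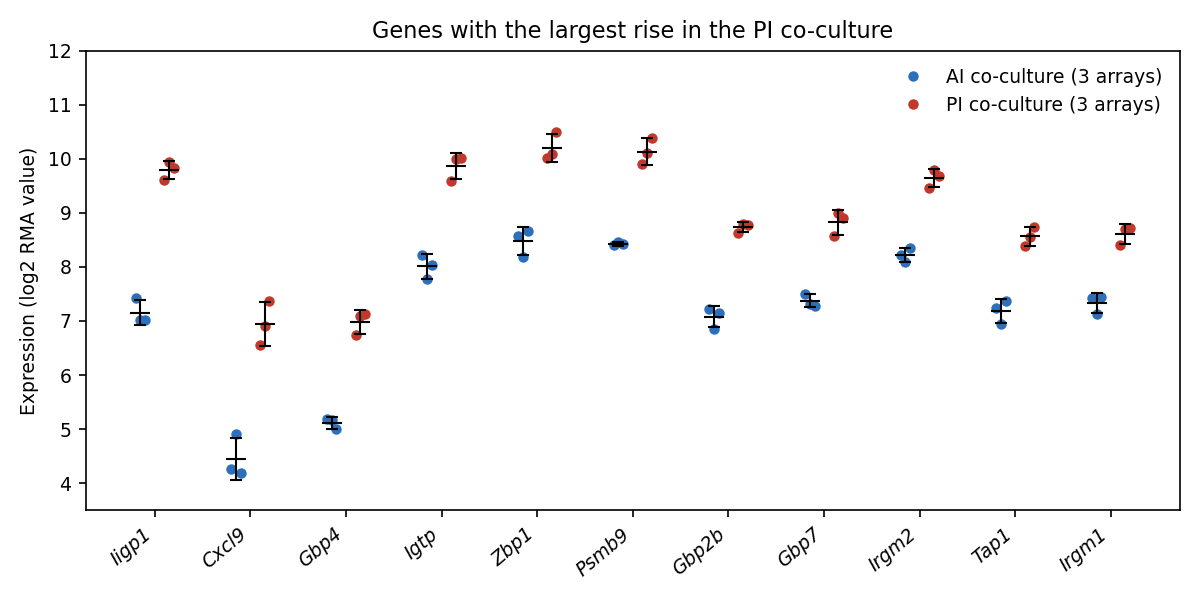
Expression (log2 RMA value) of 11 named genes with the largest rises, with 1 point per array, AI in blue and PI in red, and black bars for the mean and SD of 3 arrays. In each gene the 3 PI arrays lie above the 3 AI arrays, as the naming rule required, and the differences run from 1.28 for Irgm1 to 2.64 for Iigp1.

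No gene was lower in PI at this threshold in limma, where the smallest adjusted p of a lower gene was 0.0710, while an unmoderated test gave 2 lower genes and limma with an intensity trend and robust variance gave 7. At an unadjusted p under 0.05, limma had 947 genes higher and 775 lower, against 1169 in all by chance. The 8 lower genes with the smallest p, none past the threshold, had log2 fold changes of -0.58 for Minar2, -0.67 for Ang2, -0.77 for Mpzl3, -0.48 for C2cd2, -0.50 for Ephx1, an epoxide hydrolase, -0.63 for Il23a, a subunit of interleukin 23, -0.47 for Ccl5, a chemokine for T cells and monocytes, and -0.43 for Bok, a BCL2 family protein. Minar2 and Ang2 lay at low signal, at percentiles 15.5 and 16.3 of the genes tested by mean level. The PI and AI arrays did not overlap for 3079 genes, or 13.17% of those tested, against 10% by chance. In the authors' deposited table, 1 cluster had a q-value under 0.05, Rpl8, a ribosomal protein, with q = 0.0452 and a fold of 1.08 AI over PI. In the limma fit Rpl8 had a log2 fold change of -0.11 (adjusted p = 0.768). The count of 17 was 1 without PI replicate 2, 4 without PI replicate 3, and 7 without AI replicate 1 or AI replicate 3, against 14 without PI replicate 1 and 13 without AI replicate 2. Of 15 other settings, Iigp1 did not pass in 2, Cxcl9 in 7, and Zbp1, Gbp7, Tap1, Irgm1 and Nos2 in 8 each, all with the same direction of change.

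The group that moved most was the list of interferon-gamma-induced GTPases and regulators. Of its 21 measured members, 8 rose, 0 fell and 13 did not pass the test, and 15 passed when adjusted over the list alone. All 21 had positive log2 fold changes, with a median of 0.87, although Irf8, at 0.01, was negative after centring of the arrays, which left 20 positive. Besides Iigp1 and Cxcl9, the members that rose were the guanylate-binding proteins Gbp3 (1.26), Gbp4 (1.87) and Gbp7 (1.45), and the immunity-related GTPases Irgm1 (1.28), Irgm2 (1.42) and Igtp (1.86). The list passed camera with an adjusted p of 8.38e-34 at the preset correlation of 0.01. It did not pass with the estimated correlation of 0.261 (adjusted p = 0.0744), and it passed fry (adjusted p = 0.00778). If the higher estimate holds, the p-value at the preset correlation is too small.

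Type I interferon-stimulated genes were also higher as a list. Of 30 measured members, 2 rose, among them Zbp1, a sensor of Z-form nucleic acids, at 1.73, while 0 fell and 28 did not pass. When adjusted over the list alone, 24 members were higher and 1 was lower. Of the 30, 28 had positive values, with a median of 0.48. The camera adjusted p was 2.11e-29 at the preset correlation, against an adjusted p = 0.222 with the estimated correlation of 0.475. In fry the adjusted p was 0.0319.

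Genes of MHC class I antigen presentation were higher in PI. Of 16 measured members, 2 rose and 0 fell over all genes tested, and 15 were higher when adjusted over the list alone. Psmb9, a catalytic subunit of the immunoproteasome, rose 3.28-fold, from 8.42 ± 0.03 to 10.14 ± 0.24 (SD, n = 3 each; limma adjusted p = 0.00595). Tap1, which carries peptides into the endoplasmic reticulum, rose 2.60-fold, from 7.19 ± 0.21 to 8.57 ± 0.17 (SD, n = 3 each; limma adjusted p = 0.0208). All 16 members had positive values, with a median of 0.63. The camera adjusted p was 4.22e-28 at the preset correlation, against an adjusted p = 0.0744 with the estimated correlation of 0.16. In fry the adjusted p was 0.00778. Genes of MHC class II antigen presentation had a median of 0.06 over 10 members, 0 of them past the test, and the list did not pass camera (adjusted p = 0.451). Its member with the smallest p, the class II regulator Ciita, had a value of 0.31.

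A further 4 lists passed camera on the higher side with smaller shifts. Cell death effectors had a median of 0.18 over 21 members, of which 1 rose, Zbp1, and 5 were higher when adjusted over the list alone. Their camera adjusted p was 3.06e-07, against an adjusted p = 0.0744 with an estimated correlation of 0.008. That estimate lay below the preset 0.01, so a higher correlation did not end this call. Immune checkpoint ligands had a median of 0.11 over 17 members, of which 0 passed over all genes and 1 when adjusted over the list alone. For the checkpoint ligands the camera adjusted p was 0.0142, and the adjusted p = 0.233 with an estimated correlation of -0.035, also below the preset. H2-T23, the mouse Qa-1 molecule, had a value of 0.59 and Cd274, which encodes PD-L1, a value of 0.53, both not past the test. When members of the interferon and MHC class I lists were left out of it, the checkpoint list no longer passed (adjusted p = 0.197), nor did it without PI replicate 2 (0.05 after rounding, just above the threshold), PI replicate 3 (0.0515) or AI replicate 1 (0.0508). The neutrophil list had a median of 0.09 over 14 members, 0 past the test and 1 when adjusted over the list alone (camera adjusted p = 0.0241, adjusted p = 0.465 with an estimated correlation of 0.154). Its values of smallest p were 0.45 for S100a8 and 0.38 for Ly6c2, and it did not pass without PI replicate 2 (adjusted p = 0.0585), PI replicate 3 (0.356) or AI replicate 2 (0.114), after cyclic loess (0.0823) or a repeated quantile normalisation (0.0601), or in fry (0.354).

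The fourth of these lists held pro-inflammatory macrophage markers. Their median was 0.11 over 18 members, of which 1 rose, Nos2, and when adjusted over the list alone 1 was higher and 1 was lower. The list passed camera with an adjusted p of 0.00771 and not with an estimated correlation of -0.001 (adjusted p = 0.222), an estimate below the preset. It also did not pass when Nos2 and members of the interferon and MHC class I lists were left out (adjusted p = 0.0605), without AI replicate 2 (0.0712) or in fry (0.0927). The general macrophage list did not pass (median 0.01 over 28 members, 0 past the test, adjusted p = 0.523; Mpeg1 had a value of 0.58 and Cd14 -0.23), and neither did anti-inflammatory macrophage markers (median 0.01 over 18 members, 0 past the test, adjusted p = 0.900). Of the latter, Ccl22, a chemokine for regulatory T cells, had a value of -1.02, and Arg1, which encodes arginase, a value of 0.32, both not past the test. The depletion target Itgam, which encodes CD11b, had a log2 fold change of 0.01, Cd68 0.03, Adgre1 0.00, Csf1r -0.10, Ptprc -0.21 and Lyz2 0.19, none past the test. Macrophage transcripts had PI and AI levels of 3.65 and 3.46 for Lyz2, 4.22 and 4.20 for Tyrobp, 4.30 and 4.22 for Fcer1g, 4.34 and 4.26 for Ctss, 3.81 and 3.84 for Laptm5, 7.51 and 7.48 for Cd68, and 8.23 and 8.47 for Cd14. These levels do not give the amount of macrophage RNA in the fraction, since signals of different probe sets share no scale.

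**Figure D2:**
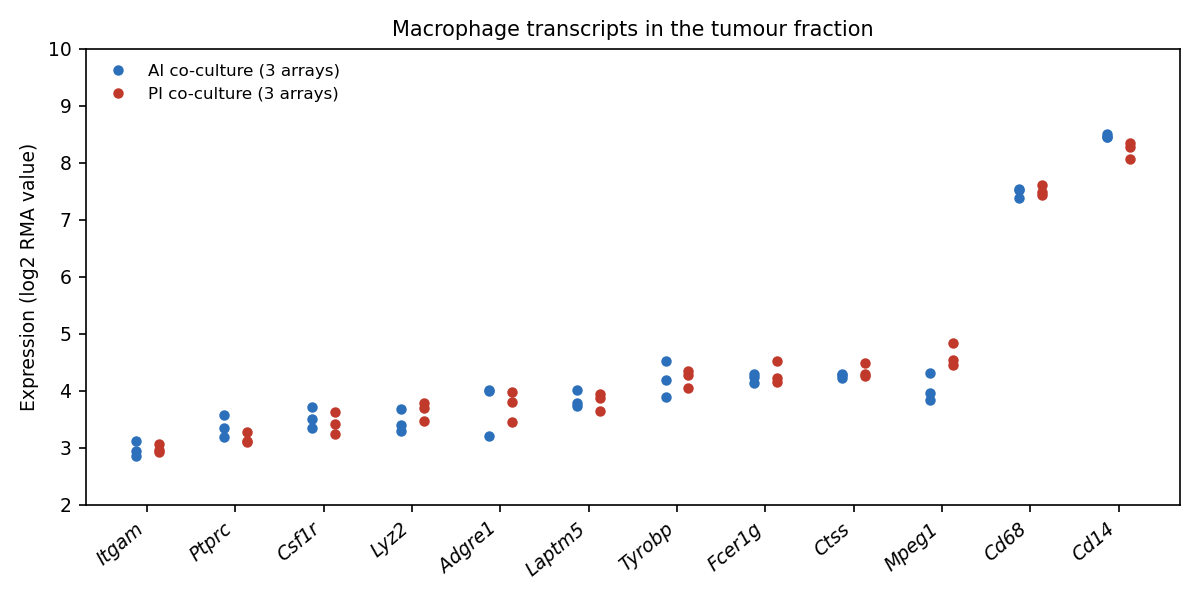
Expression (log2 RMA value) of 12 macrophage transcripts in the tumour fraction, with 1 point per array, AI in blue and PI in red. None of them passed the test between PI and AI. Levels can be compared between groups within a gene, not between genes.

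On the lower side, 4 metabolic lists passed camera with small shifts, and none of their members passed over all genes or when adjusted over the list alone. Genes of cholesterol biosynthesis had a median of -0.14, and 22 of 24 had negative values (camera adjusted p = 3.56e-05, adjusted p = 0.260 with an estimated correlation). Lss, which encodes lanosterol synthase, had a value of -0.32 and Cyp51, lanosterol demethylase, a value of -0.47. Genes of fatty acid synthesis had a median of -0.14, with 10 of 13 negative, including the desaturase Fads1 at -0.26 and the elongase Elovl6 at -0.29 (camera adjusted p = 0.00357, adjusted p = 0.331 with an estimated correlation). Genes of iron-sulphur cluster and haem enzymes had a median of -0.09, with 16 of 19 negative, including Fech, which makes haem, at -0.22 (camera adjusted p = 0.00357, adjusted p = 0.331 with an estimated correlation). Genes of oxidative phosphorylation had a median of -0.06, with 32 of 40 negative, including the complex I subunit Ndufs8 at -0.21, a member of both lists (camera adjusted p = 0.0142, adjusted p = 0.326 with an estimated correlation). Without PI replicate 1, the lists of fatty acid synthesis (adjusted p = 0.0641) and oxidative phosphorylation (adjusted p = 0.0786) did not pass. The oxidative phosphorylation list did not pass without AI replicate 2 (adjusted p = 0.0865), after cyclic loess (0.113) or a repeated quantile normalisation (0.0601), or among genes above the median level (0.0900), and in fry the first 3 of these lists did not pass (adjusted p = 0.0767, 0.0767 and 0.0556).

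**Figure D3:**
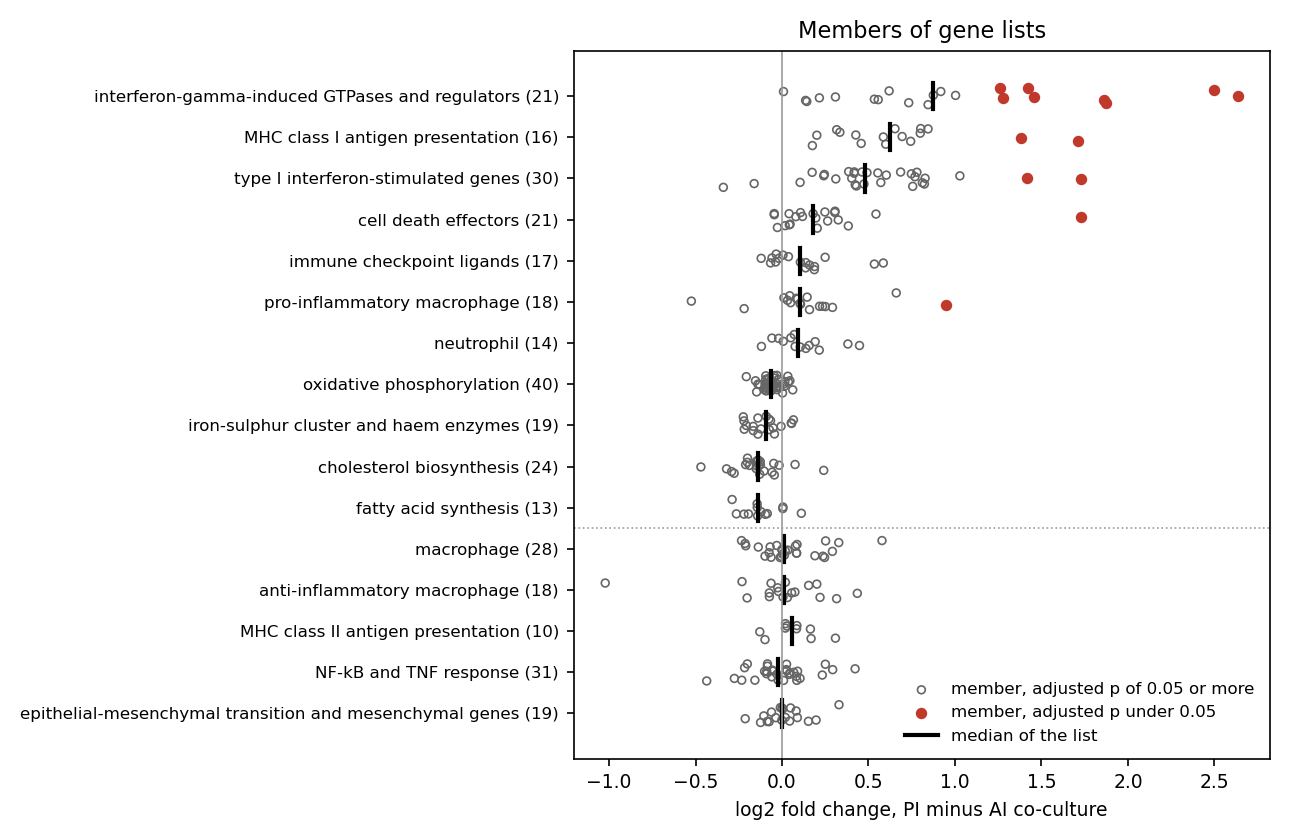
Log2 fold change (PI minus AI) of each measured member of 16 gene lists, with the number of members in brackets. Filled red points passed an adjusted p of 0.05, open points did not, and black bars are list medians. The 11 lists above the dotted line passed camera at the preset correlation, with medians from -0.14 to 0.87, and the 5 below it did not.

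Of the 41 lists tested, 11 passed camera with the preset correlation, 7 higher and 4 lower, and 0 passed with an estimated correlation. Cell death effectors, pro-inflammatory macrophage markers and checkpoint ligands lost their calls although their estimates lay below the preset. A raised correlation therefore does not account for every lost call. Fry, which tests for a shift in 1 direction without comparing a list with other genes, gave 8 lists, of which 6 were among the 11. The other 2 were ribosomal proteins (fry adjusted p = 0.0240) and growth factors and angiogenesis (0.0457), both lower, which did not pass camera (adjusted p = 0.0562 for each). Other lists that did not pass included NF-kB and TNF response genes (median -0.02 over 31 members, 0 past the test, adjusted p = 0.900), with values of 0.42 for the chemokine Cxcl2 and -0.28 for Nfkb2. Genes of epithelial-mesenchymal transition had a median of 0.00 over 19 members, 0 past the test (adjusted p = 0.994), with values of -0.21 for Itga5 and 0.20 for Cdh2. Genes of mitosis had a median of -0.04 over 29 members and p53 targets -0.07 over 23, with 0 past the test in either (adjusted p = 0.207 and 0.0562).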

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

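The test of all transcript clusters was chosen only after the result for named genes was seen. When all 41345 clusters were tested with limma, 8 passed an adjusted p of 0.05, all higher in PI, of which 5 carried 1 gene symbol and 3 carried several symbols and so lay outside the comparisons above. A pair of the 3 were annotated to both Gm17757 and Gm18853, with log2 fold changes of 1.39 and 1.42 (adjusted p = 0.0285 for each). The other was annotated to Gm4070, Gm8979, Gm8989 and Gvin1, with a log2 fold change of 1.496 (adjusted p = 0.0371), and its signal cannot be assigned to any of these genes. In each of the 3 clusters the 3 PI arrays lay above the 3 AI arrays. Of the 14308 clusters with no gene symbol, 0 passed.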

How the results depend on the processing

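Cyclic loess, the test of all clusters, and lists without interferon, MHC class I and Nos2 members were chosen only after the results were seen. The alternative of using the other deposited table was not run because its values were identical. The 17 genes remained past the threshold after quantile normalisation (20 genes), centring of arrays (18), averaging of clusters (17) and cyclic loess (21). For these genes, quantile normalisation and centring tested little, since the distributions of the arrays were already close. The median log2 fold change of all genes went from -0.01 to -0.01 and -0.05. Lists with small shifts were more sensitive. Quantile normalisation ended the camera calls of oxidative phosphorylation and neutrophil (adjusted p = 0.0601 for each), and centring took the negative members of oxidative phosphorylation from 32 to 38 of 40. Counts that moved by over 1.5 times, with the cause not tested, were 42 genes (40 higher, 2 lower; 16 of the 17 kept) among genes above the median level, 76 (69 higher, 7 lower; all 17 kept) with an intensity trend and robust variance, 2 (0 higher, 2 lower; H2-Ke6 and Rpl8) in an unmoderated test, 42 (40 higher, 2 lower) at an adjusted p under 0.1, 2 (both higher) with values floored at the 20th percentile, and 8 (all higher) with all clusters tested. With the replicate number as a block, 1 gene passed (Gm4841, higher). Whether equal numbers mark a shared mouse is not stated. Each array's deviations from its group mean were therefore correlated between PI and AI arrays. Pairs of the same number had correlations of 0.041, 0.006 and 0.057, and pairs of different numbers -0.075 to 0.038. By this measure PI replicate 2 correlated better with AI replicate 1 (0.038) than with its own number (0.006). Values this small do not settle the question, so pairing by mouse stays open. Leaving out each array in turn, which leaves fewer samples, gave 1 to 14 genes, of which 1 to 13 were higher and 0 to 1 lower, and 8 to 11 lists, of which 2 to 6 were lower. Across 15 settings, Iigp1 kept log2 fold changes of 2.56 to 2.77, with adjusted p from 2.795e-06 to 0.3232, and did not pass in 2. The other named genes did not pass in 3 (Gbp3), 4 (Gbp4 and Psmb9), 5 (Gbp2b), 6 (Igtp and Irgm2), 7 (Cxcl9) or 8 of the 15 (Zbp1, Gbp7, Tap1, Irgm1 and Nos2). The highest adjusted p was 0.4414 for Cxcl9 and 0.44 for Zbp1, Tap1, Irgm1 and Nos2. With an estimated correlation 0 lists passed (0 higher, 0 lower). In the other 15 settings in which lists were tested, 4 lists passed each time: interferon-gamma, type I interferon, MHC class I and cell death effectors. No named gene or list changed direction while past its threshold. Genes below the median level had the wider intervals.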

Other observations

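Tests chosen only after the result was seen were those of macrophage RNA differing between the groups and of the difference between the interferon lists. The other tests here were set before their values were seen, when the fold changes and list medians that prompted them were already known. The rule that macrophage transcripts at low signal decide nothing was added after their values were seen. A test of AW112010 alone and a test of an offset between arrays were also run after the result was seen and left out, since neither was able to decide anything.

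Members of the interferon and MHC class I lists differed widely in size. The genes named here were chosen after their values were seen. Cxcl10, a chemokine that shares its receptor with Cxcl9, had a log2 fold change of 0.14 (adjusted p = 0.830), and Irf1, a transcription factor induced by interferon, a value of 0.87 (adjusted p = 0.0541). B2m, the light chain of MHC class I, had a value of 0.20 from a level of 12.34 in AI, and the heavy chain gene H2-K1 a value of 0.18, both not past the test. Oasl1 was the member of the type I list that was lower when adjusted over the list alone, with a value of -0.34 (adjusted p = 0.617 over all genes).

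RNA from macrophages left in the tumour fraction is a candidate explanation for the interferon-induced genes, and it stays open. The median PI level of 6 abundant macrophage transcripts minus the median rise of the 17 genes was -3.61 on the log2 scale, which met the limit set beforehand against this explanation, but that limit was wrong because signals of different probe sets share no scale. The macrophage list's median level differed by at most 0.26 between the highest PI and the lowest AI array, against a median log2 fold change of 1.45 for the 17 genes. Most of that list lay at low signal, where added RNA may not show, and Cd68 and Cd14 had levels high enough to hide a small share, so more macrophage RNA in PI is not excluded. A response of the tumour cells to PI or to AI macrophages, or to cytokines carried over from polarisation, may also account for these genes and was not tested.

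The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 17 genes and the highest other split 0, and for lists the real split gave 11 and the highest other split 6, so 1 split gave as many in each case.

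The lower metabolic lists may reflect a level-dependent shift of abundant genes, since the median log2 fold change was -0.04 among genes of the highest of 4 equal groups by level. Among 10000 random lists matched on mean level, the list medians lay at percentile 0 for cholesterol biosynthesis and 0.07 for fatty acid synthesis. They lay at 1.56 for iron-sulphur cluster and haem enzymes and 0.43 for oxidative phosphorylation. For cholesterol biosynthesis, fatty acid synthesis and iron-sulphur cluster and haem enzymes, this argues against a level-dependent shift of abundant genes as the whole cause. The oxidative phosphorylation list did not pass camera after cyclic loess (adjusted p = 0.113) or a repeated quantile normalisation (0.0601). It also did not pass among genes above the median level (0.09), so a level-dependent shift stays open for oxidative phosphorylation. Random lists do not carry the correlation between genes of a pathway. The estimated correlation was 0.092 for cholesterol biosynthesis, 0.121 for fatty acid synthesis, 0.109 for iron-sulphur cluster and haem enzymes and 0.026 for oxidative phosphorylation. Each exceeded the preset 0.01, so shared variation within each pathway stays open. That 0 lists passed with an estimated correlation does not show it, since cell death effectors, with an estimate of 0.008, also lost their call.

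A hypothesis is that interferon-gamma-type genes differed more between the PI and AI co-cultures than type I interferon genes. The medians differed by 0.39 (0.87 over 21 genes against 0.48 over 30), with p = 0.00169 in a two-sided permutation test with 100000 reassignments of members to the lists. The test treats genes as independent, which they are not, and many genes of either list respond to both kinds of interferon, so it does not say which interferon may have acted.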
